A study of Nicotiana tabacum with 6 samples.

How the data were processed

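Gene expression was measured in 6 samples of total RNA from suspension-cultured tobacco (Nicotiana tabacum) cells with 1-colour Agilent arrays. 3 samples came from the wild-type line SL and 3 from ALT301, an aluminium-tolerant line that the series title pairs with SL as isogenic. Per the labels' protocols, both lines were grown at 25 °C in the dark with shaking at 100 rpm in a modified Murashige-Skoog medium, without an aluminium treatment, and all samples are labelled as logarithmic phase. Per the labels' protocols, 200 ng of total RNA was amplified and labelled with Cy3. The labels number the replicates but do not say whether they were separate cultures, so the p-values measure the spread between these samples, which may be technical.

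The authors deposited 1 scanner file per array, written by Agilent Feature Extraction 11.5.1.1 per the file headers. The deposited signal intensities are linear values, background-subtracted and spatially detrended within each array, and not yet scaled between arrays. The authors also deposited a table of log2 values for the same 6 arrays. How it was made is not given in the sources used here. Set against the scanner files, these log2 values correlated at 0.999 or higher, array by array, with log2 signal scaled at the 75th percentile and centred on each probe's median over the 6 arrays, so scale, centring and direction could all be worked out. The medians of its 6 columns were -0.03, -0.0033 and 0.03 for the SL arrays and 0.03, -0.01 and -0.01 for the ALT301 arrays. That table served as an alternative, and 0 columns of per-sample values were left unmapped.

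Control spots were left out and spots flagged by the scanner software as non-uniform or as population outliers (14 to 56 probes per array) were set missing. No spot was saturated. The log2 processed signals of the spots of 1 probe were averaged (11 probes had 5 spots each, the others 1), and each array's 75th percentile was subtracted. A level of 0 is therefore the 75th percentile of the array. Of 43759 probes, the 30942 that were well above background on at least 3 of the 6 arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, line as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. "Called" means past that threshold, and differences are ALT301 minus SL on the log2 scale. Where a probe was not well above background on any array of a line, its difference was written as a lower bound. The bound holds for the processed signal and can be higher than the difference under another background correction. It is the mean log2 signal of the bright line minus the mean, over the dim line's arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array. Intervals around shares of probes are exact binomial 95% intervals and treat probes as independent, which probes of 1 transcript are not.

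The arrays lay on 2 slides scanned separately: slide 1 held replicates 1 and 2 of both lines, and slide 2 held replicate 3 of both. Deviations from the line means correlated at 0.33, 0.14 and 0.10 between the same-numbered arrays of the 2 lines, and lay between -0.21 and 0.09 for arrays with different numbers. By a limit of 0.1 for every pair (the lowest was 0.1048), the numbers were taken to pair the arrays. This pairing comes from the data and the labels' numbers, since nothing in the labels says what a number shares. The replicate number and the slide were each tried as a block.

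The scanner files name each probe by a probe name and a sequence identifier (40425 distinct identifiers, 2903 of them with several probes), without a gene name or description. None of the identifiers matched the RefSeq gene table of assembly ASM71507v2 (0 of 40425), and 894 probes carried only their probe name. The 30 gene lists, the test of description words and the rule for naming genes by function, all fixed before the data were examined, therefore could not be run. In place of named genes, the 2 probes with the highest and the 2 with the lowest fitted log2 difference are given by identifier, among called probes whose 3 arrays of 1 line all lay above the 3 of the other. The fitted difference of a probe at background in 1 line depends on values below the detection limit, so these 4 are not shown to be the largest differences. Probe sequences were not used here, so whether a probe tells apart the near-identical gene copies of this polyploid species is open.

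Alternatives fixed before the data were examined were median scaling, quantile normalization, the deposited table, no filter on dim probes, a filter requiring all 6 arrays, flagged spots kept, eBayes with trend and robust, both blocks, slide 1 alone and leaving out each array. Added afterwards was normexp background correction (offset 50) on the median spot signal, since the files hold no mean spot signal. The offset is added to every signal, so by itself it shrinks the fold differences of dim probes. Scaling on the E1A spike-in control probes, with and without the slide as a block, was also added afterwards. So was leaving out each array from the count of probes detected in 1 line only. limma was tested on simulated data for this comparison, with 30859 probes at their measured means and spreads and 50 probes changed at each fold. It called 0% of the probes changed 1.2-fold, 38% of those changed 1.5-fold, 70% of those changed 2-fold and 94% of those changed 4-fold. There were 8 calls among 30659 unchanged probes, so that 7.34% of its calls were false, above the 5% the threshold aims at. With 8 false calls in 1 run, whether the share exceeds 5% in general is not settled. With 15429 probes changed 2-fold it called 93.3% of them, and 2.74% of its calls were false. Both simulations drew the errors independently for each probe, so an error shared by the probes of an array was not covered.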

Results

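Transcript levels in cultured tobacco cells were compared between the wild-type line SL (n = 3 arrays) and the aluminium-tolerant line ALT301 (n = 3 arrays), both grown without added aluminium. Aluminium ions are toxic to plant cells in acid soil. The question the design addresses is which transcripts differ between the 2 lines under normal growth. The arrays carried 43759 probes for tobacco transcripts. The median processed signal lay between 248.7 and 325.3 intensity units per array. The share of probes well above background was 69.7% ± 1.26 (SD, n = 3) in SL and 69.0% ± 1.33 (SD, n = 3) in ALT301, a difference smaller than the SD within each line (two-sided exact permutation test, p = 0.7, where the smallest p that 3 against 3 arrays allow is 0.1). With 3 arrays per line, the number of arrays limits the precision.

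The 2 lines separated by more than the replicates did. Across the tested probes, arrays of 1 line correlated at 0.992 to 0.996 and arrays of different lines at 0.910 to 0.916 (Pearson's r across probes, which are not independent replicates). The first principal component carried 91.2% of the variance between arrays and the second 3.26%. The median SD between arrays of 1 line was 0.11 log2 units, and the median absolute difference between the lines was 0.58. Spots of the same probe within an array differed by a median SD of 0.06.

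Of 30942 tested transcript probes, 22048 (71.3%) differed between ALT301 and SL at an adjusted p below 0.05 (limma, Benjamini-Hochberg). 10600 of them were higher in ALT301 and 11448 were lower. The count depended on the scaling: scaled on the E1A spike-in probes, whose level varied between arrays, 4259 (13.8%) were called, and 13620 (44.0%) with the slide as a block as well. Most of the differences were small: 13424 of the called probes differed by less than 2-fold. 4129 probes were at least 2-fold higher in ALT301 and 4495 at least 2-fold lower, together 27.9% of the probes tested. In 21982 of the called probes the 3 arrays of 1 line all lay above the 3 of the other. Such separation was seen in 75.8% of the tested probes, and arrays that do not differ give it in 10% by chance. That 10% takes all arrays as exchangeable and leaves out the pairing by replicate number. The called probes carried 20124 of the 28184 identifiers tested.

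The balance between higher and lower depended on the scaling and on the background correction. Calls split 48.1% higher under the 75th percentile, 50.3% higher under the median and 50.6% higher under normexp background correction. At 2-fold, median scaling gave 4347 higher and 4296 lower and normexp 3363 and 3078, so the direction at 2-fold turned. Scaled on the E1A spike-in probes, the median difference over all tested probes moved from -0.04 to -0.24 log2 units. With the slide as a block as well, 4716 probes were called higher and 8904 lower, a split of 34.6% higher. Differences given here are relative to each array's 75th percentile.

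**Figure D1:**
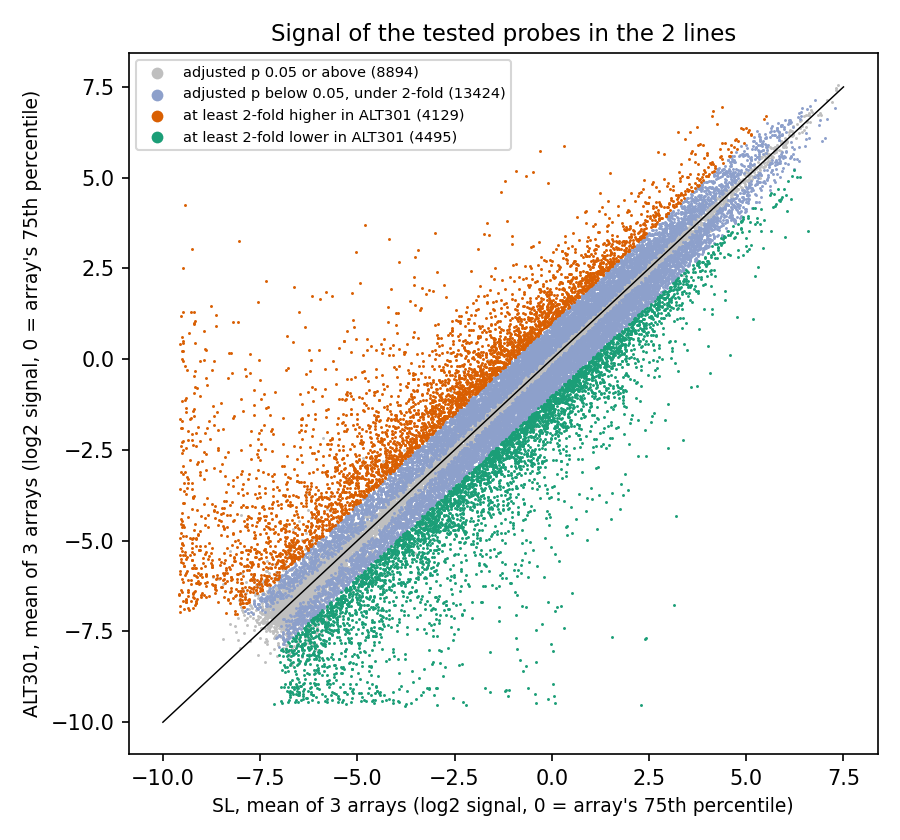
Each point is 1 of the 30942 tested probes, plotted by its mean log2 signal over the 3 SL arrays (horizontal axis) and over the 3 ALT301 arrays (vertical axis), where 0 is the array's 75th percentile and the black line marks equal signal. The 4129 probes at least 2-fold higher and the 4495 at least 2-fold lower in ALT301 lie on both sides of the line in each of 10 classes of signal. Among the 100 brightest probes, 2 were at least 2-fold higher and 0 at least 2-fold lower. A strip of probes near -9.5 on either axis was at background in that line.

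Large differences leaned towards higher signal in ALT301. At least 4-fold differences were found for 1459 probes higher and 1338 lower. At least 8-fold, 697 were higher and 531 lower. At least 16-fold, 384 were higher and 244 lower, so that 61.2% were higher in ALT301 (95% interval 57.2% to 65.0%). At least 32-fold, 233 were higher and 115 lower, which is 67.0% (61.7% to 71.9%). These counts rest on fitted differences. With lines at background put at their bound, 302 were at least 16-fold higher and 184 at least 16-fold lower. Among probes well above background on all 6 arrays, where both lines were measured, 134 were at least 16-fold higher and 96 at least 16-fold lower. Under normexp the counts fell to 167 and 81. Scaled on the spike-in probes, 353 were at least 16-fold higher and 285 at least 16-fold lower.

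**Figure D2:**
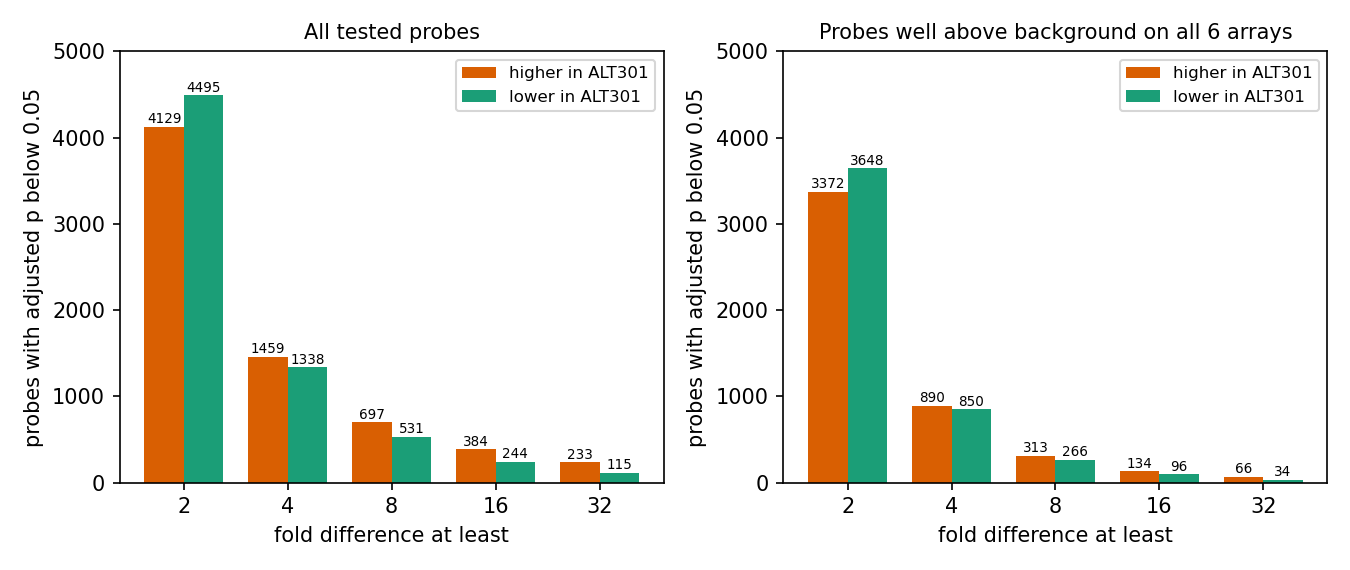
Number of called probes (adjusted p below 0.05, vertical axis) with at least the fold difference on the horizontal axis, for all tested probes (left) and for those well above background on all 6 arrays (right). In this processing lower probes outnumber higher ones at 2-fold (4495 against 4129), and higher probes outnumber lower ones at 32-fold (233 against 115).

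A group of 1168 transcript probes was detected in 1 line only. 546 of them (535 identifiers) were well above background on all 3 ALT301 arrays and on no SL array, and the others (607 identifiers) on all 3 SL arrays and on no ALT301 array. The lower bound of the difference in processed signal had a median of 3.72-fold for those detected only in ALT301 (quartiles 2.11 and 13.9) and 2.29-fold for those detected only in SL (quartiles 1.65 and 4.78). Bounds of at least 16-fold were found for 127 probes detected only in ALT301 and 53 detected only in SL. Bounds of at least 64-fold were found for 58 and 23. Below a 2-fold bound lay 130 and 252, for which a difference of 2-fold was not shown. With detection taken as a signal that is positive and significant, a more lenient limit, 268 probes were detected only in ALT301 and 276 only in SL.

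**Figure D3:**
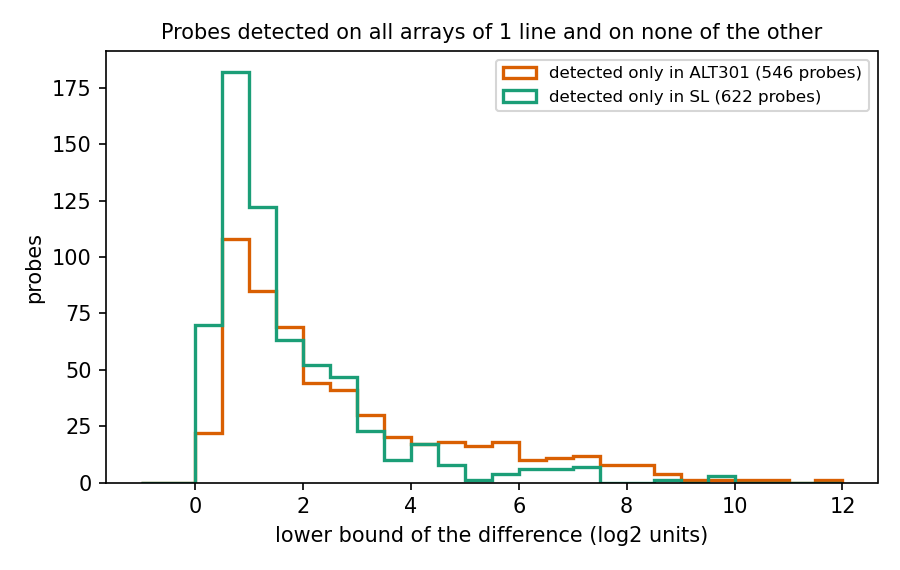
Distribution of the lower bound of the difference (horizontal axis, log2 units) for the 546 probes detected on all ALT301 arrays and no SL array and those detected on all SL arrays and no ALT301 array, 1168 in all, counted in steps of 0.5 log2 units (vertical axis, probes). Low bounds are more frequent among probes detected only in SL, and bounds of at least 64-fold, 6 log2 units, were reached by 58 probes detected only in ALT301 and 23 detected only in SL.

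The 4 probes with the highest and lowest fitted differences were all detected in 1 line only, where the fitted difference of a line at background gives no order. By their lower bounds they ranked 1 and 3 among probes detected only in ALT301, and 3 and 2 among those detected only in SL, in the order given here. The adjusted p-values below belong to the fitted differences, which rest on values below the detection limit in 1 line. The bounds themselves were not tested. Probe A_95_P028391 (identifier TA14148_4097) had a level of 4.25 ± 0.04 log2 units in ALT301 (SD, n = 3) and was not well above background in SL, a difference of at least 2926-fold in processed signal (limma, adjusted p = 1.13e-08). Probe A_95_P001346 (FG623263) had a level of 3.03 ± 0.07 in ALT301 and was not well above background in SL, at least 1257-fold in processed signal (limma, adjusted p = 1.13e-07). In the other direction, A_95_P010431 (DW003182) had a level of 2.30 ± 0.01 in SL and was not well above background in ALT301, at least 747-fold lower in processed signal (limma, adjusted p = 1.13e-08). Probe A_95_P006841 (NP916736) had a level of 2.39 ± 0.13 in SL and was not well above background in ALT301, at least 792-fold lower in processed signal (limma, adjusted p = 2.11e-07). Under normexp background correction with an offset of 50, the log2 differences of the 4 probes, in the order given, were 9.92, 8.63, -7.93 and -7.70. They were smaller than the bounds in processed signal, 11.515, 10.30, 9.545 and 9.629 log2 units. The mean processed signals of these probes in the dim line were 5.06, 5.88, 4.42 and 15.8 units, all below the offset. An offset of this size shrinks such differences by itself, so the values under normexp do not test the bounds. The array files do not pair these identifiers with gene names, so the transcripts are given by identifier.

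The share of called probes was lowest among the dimmest. In 10 classes of signal, from dim to bright, it was 47.9% in the dimmest, 79.9% in class 7, the highest, and 75.2% in the brightest. The dimmest and brightest had a median SD between replicates of 0.34 and 0.07 log2 units. The share called with at least 2-fold was 33.4% in the dimmest class, 37.9% in class 3, the highest, and 14.9% in the brightest. With normexp background correction the shares of the dimmest and brightest classes were 6.91% and 15.1%, the reverse order. The offset of 50 in that correction shrinks the fold differences of dim probes by itself. The lower share in the dimmest class under normexp therefore does not show which order holds. In the brightest class, 272 probes were at least 2-fold higher and 190 at least 2-fold lower, a direction that turned under spike-in scaling with the slide as a block (172 and 300). In the dimmest class, 451 were higher and 582 lower, which turned under normexp background correction (142 and 72). Of the 100 brightest probes over all arrays, 44 were called higher and 14 lower in ALT301 (35 and 27 under quantile normalization, 3 and 4 under spike-in scaling with the slide as a block), and 2 differed by at least 2-fold, both higher. The 100 brightest probes of each array held 10.5% ± 0.60 of the summed signal in SL and 10.8% ± 0.30 in ALT301 (SD, n = 3, two-sided exact permutation test, p = 0.6).

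Both slides gave the difference between the lines. On slide 1 alone (2 arrays per line), 20522 probes were called by limma. Of the 20508 of these with a value on slide 2, 20111 (98.1%) had the same sign there, where 1 array of each line gives a difference with no test. Of 8462 probes called on slide 1 with at least 2-fold, 7441 (87.9%) differed by at least 2-fold in the same direction on slide 2. The log2 differences of the 2 slides correlated at 0.950 over the tested probes (Pearson's r across probes). With the slide as a block 22259 probes were called.

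Probes that share an identifier gave an internal check. For the 2089 identifiers with exactly 2 tested probes, the log2 differences of both probes correlated at 0.840 (Pearson's r across identifiers). Both probes were called for 1412 of these identifiers, in the same direction for 1357 and in opposite directions for 55 (3.90%, against 49.9% for random pairs of called probes). Of the 465 identifiers where both probes differed by at least 2-fold, 7 had opposite directions. For 355 identifiers only 1 of the 2 probes was called.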

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

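One control probe, eQC-40 (10 spots per array), gave signal on all 6 arrays above every negative-control spot of the same array, although it is not part of the comparison between the lines. Relative to the 75th percentile its mean log2 signal was -3.51 ± 0.20 in SL and -4.27 ± 0.13 in ALT301 (SD, n = 3), a difference of -0.76 log2 units with all 3 ALT301 arrays below all 3 SL arrays (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 arrays allow). The control probes RC3, RC8, RC11 and ETG10_195139 reached the same p in this test, with ALT301 higher. They did not lie above every negative-control spot. Many control probes were tested in this way without adjustment for their number, so some can reach a p of 0.1 by chance. The 3 related control probes eQC-39, eQC-41 and eQC-42 stayed near the negative controls, at mean log2 signals of 2.56, 2.74 and 2.65 in SL before scaling, against 2.48 for the negative controls. What the probe detects was not tested.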

How the results depend on the processing

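Under every alternative run on the called probes, no probe called in the main comparison was called in the opposite direction, and the 4 probes given by identifier kept their direction and stayed past the threshold wherever they were tested. Under normexp their log2 differences shrank from 13.70, 12.29, -11.84 and -10.09 to 9.92, 8.63, -7.93 and -7.70, each smaller than its bound in processed signal. The offset of 50 shrinks the differences of probes this dim in 1 line by itself, so this does not test the bounds. The count of 22048 called probes lay between 20487 and 21624 when 1 array was left out in turn, with 9818 to 10248 higher and 10604 to 11376 lower. The count at 2-fold lay between 8481 and 8676 (4021 to 4181 higher, 4318 to 4527 lower). Probes detected in 1 line only numbered 1303 to 1438 with 1 array left out (576 to 695 only in ALT301, 662 to 849 only in SL). These counts exceed 1168 because the rule then asks for fewer arrays. Without SL replicate 1 the balance turned, with 695 only in ALT301 and 662 only in SL. With any other array left out, more were detected only in SL. The replicate block called 22094 probes, with 96.5% of the main calls among its own in the same direction, and changed no count by more than 1.5 times. Slide as a block, quantile normalization, median scaling, the deposited log2 table, flagged spots kept, and eBayes with trend and robust called 69.2% to 72.0%, no filter 49.6% of 43758 probes, and the filter on all 6 arrays 73.8% of 27662. The exception was scaling on the E1A spike-in probes, which called 4259 probes (1701 higher, 2558 lower), all of them at least 2-fold. With the slide as a block as well it called 13620, of which 4716 were higher. The spike-in level differed between slides by 1.14 log2 units and between replicates of a line by an SD of 0.71. With the slide as a block its residual SD was 0.30. This scaling adds the spike-in variation to every probe of an array: 19.1% of the main calls stayed called without the block and 59.0% with it. Taking detection as positive and significant signal gave 544 probes detected in 1 line only (268 only in ALT301, 276 only in SL). The counts at 16-fold moved with the treatment of low signal: normexp gave 167 higher and 81 lower, and the filter on all 6 arrays 134 and 96. Low signal over background limits the dim probes, whose fitted differences depend on the floor. The planned normexp on the mean spot signal, the gene lists and the test of description words were not run, since the files used here hold neither that signal nor descriptions.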

Other observations

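The tests of the splits for the called probes, of scaling, of loss in ALT301, of slide 1 as a check on slide or scan and of the identifier prefixes were chosen after the results were seen, as was the spike-in scaling. Median scaling, quantile normalization, the slide block and slide 1 alone were planned as alternatives, and the split test for probes detected in 1 line only was set before. Probes grouped by the prefix of their identifier differed in direction, in the main processing, the only one given for this comparison. Among probes called with at least 2-fold difference, 39.8% of those whose identifier starts with BP were higher in ALT301 (671 higher, 1017 lower, 95% interval 37.4% to 42.1%). For the prefix AM the share was 35.4% (28.4% to 42.9%). For CV it was 63.0% (57.8% to 68.0%, 225 higher, 132 lower) and for EH 55.4% (50.8% to 59.9%). Over the 9 prefixes with at least 500 tested probes, Fisher's exact tests of 1 prefix against all other probes gave adjusted p of 8.01e-13 for BP, 2.49e-08 for CV, 0.00146 for AM and for EH and 0.000341 for TA (52.3% higher), and between 0.0527 and 0.505 for the rest. Probes of 1 transcript are not independent, so these p-values are too small. Compared within 10 classes of signal level, the odds ratio for being higher was 0.694 for BP and 1.90 for CV. What the prefixes stand for was not used here.

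That 22048 of the tested probes differed was weighed against technical sources. Position on the array accounted for 0.44% of the variance of the log2 differences over 100 blocks of spots, where chance gives 0.32%. Within slide 1 alone 66.5% of the tested probes were called. Each slide held as many arrays of 1 line as of the other. A shift shared by a whole slide or scan could therefore not by itself make a line difference, and this count does not test it. Differences between arrays within a slide were not tested. A single scaling factor per array moves every probe alike, and the differences spread over probes by 9.93 times the median standard error of 1 difference. The first prediction on scaling, written after results were seen, was that fewer than 50% of the tested probes would be called under another scaling if scaling was the source. That is what came out, 13.76% under spike-in scaling and 44.0% with the slide as a block, and the spread test was written in its place after that. The spike-in level varies by an SD of 0.71 between replicates, part of it between the slides. With the slide as a block its residual SD was 0.30 log2 units, so the larger SD does not apply to the 44.0%. In both forms this scaling adds the spike-in variation to every probe of an array. Calls can then end without a change of the differences between probes, so the first prediction cannot tell. The spread argues only against 1 factor for all probes of an array. The direction balance stays open: the share of higher calls fell to 39.9% under spike-in scaling and to 34.63% with the slide as a block as well. With the slide as a block, the spike-in shift between the lines was 0.20 log2 units with a standard error of 0.24, so scaling and a real imbalance cannot be told apart. Of the 10 splits of the arrays into 3 and 3, only the real 1 called any probe (22048, and 8624 at 2-fold). The others called at most 0 and 0, and 3 of them part all 3 pairs as the real one does. Each of the others has arrays of both lines on both sides, so a line difference adds to its spread within sides. Their counts of 0 follow from that and do not measure what chance gives. In addition, 10 splits are too few for a share under 0.05. A difference between the lines in the state of the cultures at harvest, beyond the growth phase in the labels, was not tested.

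The lean of the largest differences towards ALT301 was set against the background floor. With every line at background put at its bound, 302 probes were at least 16-fold higher and 184 at least 16-fold lower, a ratio of 1.641 (62.1% higher, 95% interval 57.7% to 66.5%), which argues against unequal floors as the source. One hypothesis for transcripts detected in 1 line only is that ALT301 lost genome segments or silenced genes when the line arose, which as the main source would leave more transcripts missing in ALT301. With 1 probe per identifier, 53.15% of all were detected only in SL (607 against 535, 95% interval 50.2% to 56.1%), while under the more lenient detection limit 50.7% of the probes were (46.45% to 55.01%), so the hypothesis can be neither excluded nor supported. An earlier form of this test used only bounds of at least 16-fold and was dropped, since the lean of the 16-fold differences had been seen when it was written and a split by size restates it. In that form 28.7% of those with a bound of at least 16-fold were detected only in SL (50 against 124 only in ALT301, 95% interval 22.1% to 36.1%). Among those with a bound under 16-fold, 57.5% were detected only in SL (557 against 411, 95% interval 54.4% to 60.7%). The 1168 probes detected in 1 line only compare with at most 160 in the other 9 splits, again too few splits for a share under 0.05. That highest split puts the 3 arrays with the most detected probes on 1 side. Each of the other splits mixes the lines, so no probe detected in 1 line only can count in it, which lowers its count. The comparison therefore does not measure what chance gives.

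Pairs of probes with 1 identifier and opposite calls were compared with same-direction pairs. A candidate explanation is that 1 of the 2 probes lies near background. The prediction set beforehand was a dimmer probe at least 1 log2 unit lower in opposite pairs, by medians. The dimmer probe of the 55 opposite pairs had a median level of -1.575 log2 units and that of the 1357 same-direction pairs -0.31. The difference of -1.261 met the prediction. Both medians lie well over the background limit of about -7.2. The opposite pairs whose dimmer probe lies at or above their median are therefore not near background. That part of the pairs is picked by its own signal, so for the other opposite pairs the explanation stays open. Gene copies or transcript forms that 1 probe detects and the other does not remain open and were not tested.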
